A study of Homo sapiens with 12 samples.

How the data were processed

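RNA was sequenced from primary human endometrial stromal cells, the fibroblast-like cells of the uterine lining that turn into decidual cells in pregnancy. Cells from 3 donors were each placed in 4 groups, which gave 12 libraries, 3 per group. Per the labels' protocols, cells received 60 nM of a non-targeting siRNA (siNT), an siRNA against the progesterone receptor gene PGR (siPGR) or an siRNA against the transcription factor gene FOXO1 (siFOXO1) for 48 h. They were then treated for 72 h, with the medium renewed at 48 h. The treatment, called EPC here, held 10 nM 17β-estradiol, 100 nM medroxyprogesterone acetate (a synthetic progestin) and 1 mM cAMP, a combination that induces decidualization in culture. One further siNT group received vehicle. Libraries were prepared with a TruSeq kit from total RNA, per the labels' protocols. Whether the kit or the counting kept the strand is not given in the sources used here, so a gene and an antisense or overlapping neighbour cannot be separated.

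The submitters' processing notes name the build hg19 and the tools TopHat2 2.0.0, Bowtie 0.12.7, HTSeq, R 2.14.0 and edgeR 2.4.6, with no settings. The files analysed were the authors' own comparison tables, 1 for each of 3 comparisons: siNT with EPC against siNT with vehicle (the EPC response), siPGR with EPC against siNT with EPC (the PGR knockdown), and siFOXO1 with EPC against siNT with EPC (the FOXO1 knockdown). Each deposited table gives, per the file headers, a log2 fold change and the mean log2 CPM (read counts scaled to library size) of a gene over the libraries compared. The authors' likelihood-ratio score, its p-value and a false discovery rate stand beside them, per the file headers. In each deposited table the p-value equalled the upper tail of a chi-square distribution with 1 degree of freedom at the likelihood-ratio score. The deposited false discovery rate equalled a Benjamini-Hochberg adjustment of the p-values over all genes of the table. It is called the adjusted p here. Whether the authors' edgeR model held a term for the donor is not given in the sources used here. The tables hold no value per library, so the depth of each library is unknown and no spread between replicates can be computed. Every fold change, level and adjusted p of a single gene below is therefore the authors' own.

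From these values the following was computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. A gene was called at an adjusted p under 0.05 in the authors' deposited table. This is the form of test set, before the data were examined, for tables without counts. An implied standard error (SE) was taken as the absolute log2 fold change divided by the square root of the likelihood-ratio score, where that score was at least 0.01. It is an approximation that stands for the error in the authors' fit, not for a measured spread. The CPM of each of the groups compared was worked out from the fold change and the mean, with both groups weighted equally. These implied CPM of the siNT EPC group, which enters all 3 tables, differed between tables by a median of 0.0116 to 0.0245 on the log2 scale over 13611 genes. Where an implied CPM lay under 0.1, the size of the fold change depends on the offset of the authors' fit. Such genes are named as near zero. Symbols are those of the tables, with the current symbol added once where it differs, from the RefSeq gene table of GRCh38.p14. No coordinates are printed, because the tables give none and the reference is of another build.

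Gene groups were 31 lists written from textbook knowledge before the data were examined. They covered decidual, hormone, signalling, matrix, stress and metabolic genes, and markers of other cells of the endometrium. Each list was tested against all other genes with cameraPR in limma 3.58.1 (R 4.3.3). The statistic was the square root of the likelihood-ratio score with the sign of the fold change, the preset correlation between genes was 0.01, and the adjustment ran over the 31 lists of a comparison. An estimated correlation needs values per library, so a preset correlation of 0.05 was used as the stricter alternative. Members past 0.05 are counted over all genes tested and, in those words, adjusted over the list alone. Tested on simulated data for the EPC response with 13815 genes, the list test recovered 93.7% of lists shifted by 1 unit of the statistic, and 23% of lists shifted by 0.5. It called 0.691% of unshifted lists at the larger shift. The simulated statistics were independent between genes and less spread than the measured ones, so these rates need not hold here. A list that did not pass may therefore still be shifted.

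All 3 comparisons use the siNT EPC libraries, so their errors are shared. Overlaps of calls are given beside the number expected of independent lists and the number from 100 simulations of unchanged groups against shared libraries. Without effects hardly any gene is called, so the simulated number does not show what the sharing adds among changed genes. In these simulations, the statistics of a gene had a correlation of 0.5 for both knockdowns, and -0.5 for the EPC response with a knockdown. They took the groups as otherwise independent, although the same 3 donors entered each group. Covariances of log2 fold changes are given beside the simulated ones. The difference between the knockdowns is the log2 fold change for siFOXO1 minus that for siPGR, in which the shared group cancels. Its main form has no test and counts genes that differ by at least 1 on the log2 scale. A test added after the data were seen divides the difference by the root of the summed squared implied SEs. Where a gene had no implied SE, the median of genes of similar expression stood in for it. Summing the SEs ignores the shared group, so this test is conservative if the implied SEs are right. The simulation below draws errors with these SEs and cannot check them. On simulated data with 13693 genes it recovered 17.1%, 77.9% and 96.6% of planted differences of 0.5, 1 and 2, and gave an unadjusted p under 0.05 for 0.544% of unchanged genes.

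The rule for named genes was written before the data were examined. It takes both knockdown targets, a panel of 8 genes (PRL, IGFBP1, WNT4, BMP2, HAND2, ZBTB16, FKBP5 and IRF4), and the 5 highest and 5 lowest fold changes among called genes at or above the median expression. It adds 3 members of each of the 6 lists with the smallest p, and the 5 genes of each direction that lead each overlap. The 5 genes at each end of the difference between knockdowns, and all genes outside the rule, were chosen after their values were seen. Genes outside the rule are named as further members or stand in the closing section. Left out were comparisons that need values per library: a fit with the donor as a block, leaving out each replicate, other splits of the libraries, other count models and other normalizations of counts. Alternatives that were run were an adjusted p under 0.01 or 0.1, a minimum log2 fold change of 1, leaving out the 25% of genes with the lowest expression, Bonferroni adjustment, other settings of the list test, centring on the 25% most expressed genes, and leaving the knockdown target out of the lists. Each printed log2 fold change is followed, where given, by ± its implied SE.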

Results

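The series measured mRNA in primary human endometrial stromal cells of 3 donors, in which PGR or FOXO1 was knocked down before decidualization. The 4 groups, each of 3 libraries, were siNT with vehicle, siNT with EPC, siPGR with EPC and siFOXO1 with EPC. EPC is the mix of 17β-estradiol, medroxyprogesterone acetate and cAMP that turns stromal cells into decidual cells in culture. The authors' deposited tables cover 13815 genes for the EPC response, 13953 for the PGR knockdown and 13787 for the FOXO1 knockdown, with 13611 genes in all of them. Depth per library is unknown, because the tables hold no counts. Errors after ± are SEs implied by the authors' likelihood-ratio scores, and adjusted p-values are the authors' edgeR values unless a gene list is named.

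The knocked-down genes come first, because they check the labels. In the authors' deposited table for siPGR, PGR fell by 2.14 ± 0.14 on the log2 scale (adjusted p = 7.11e-51), which left 22.6% of its mRNA. FOXO1 fell by 1.95 ± 0.14 in the authors' deposited table for siFOXO1 (adjusted p = 2.48e-43), which left 25.8%. Neither knockdown moved the other target past the threshold. FOXO1 had a log2 fold change of -0.17 ± 0.14 under siPGR (adjusted p = 0.365), and PGR one of -0.10 ± 0.11 under siFOXO1 (adjusted p = 0.684), both from the authors' deposited tables. EPC raised FOXO1 by 2.90 ± 0.16 (adjusted p = 3.5e-72), from an implied 127 to 945 CPM, while PGR had a log2 fold change of 0.15 ± 0.12 (adjusted p = 0.391) in the same authors' deposited table. Across the separately normalized comparisons, FOXO1 after siFOXO1 stood at an implied 244 CPM, still above its vehicle level. PGR after siPGR stood at an implied 45.8 CPM, against 186 in vehicle.

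The first comparison asked what EPC changed in cells with the non-targeting siRNA. EPC raised the genes that mark decidual cells, together with IGF1, the smooth muscle coactivator MYOCD and the peptide hormone gene SST. It lowered almost every cell cycle gene listed. Of 13815 genes, 4061 passed 0.05 in the authors' deposited table, 1892 higher and 2169 lower with EPC, and 579 and 668 of them changed at least 2-fold. Called genes above the median expression with the highest log2 fold changes in the authors' deposited table were SST (9.18 ± 0.48), MYOCD (6.34 ± 0.22), IGF1 (6.23 ± 0.17), C6orf176 (now LINC00473, 5.78 ± 0.18) and ID4 (5.25 ± 0.18). The lowest there were SLC7A14 (-4.64 ± 0.16), the G-protein signalling regulator RGS4 (-4.60 ± 0.24), the matrix protease MMP11 (-3.92 ± 0.15), ATP8B1 (-3.34 ± 0.16) and the tight junction gene CLDN11 (-3.16 ± 0.15).

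Of 22 measured decidual markers, 17 rose and 1 fell with EPC (17 and 2 adjusted over the list alone). The list had a median log2 fold change of 2.37 (camera adjusted p = 1.91e-42). IGFBP1 and PRL, the secreted products most used to follow decidualization, rose by 8.78 ± 0.43 and 6.13 ± 0.59 in the authors' deposited table. Both lay near zero in the vehicle group, at an implied 0.0295 and 0.0265 CPM, so the size of these folds depends on the authors' fit. With EPC, PRL was still at only 1.86 CPM and IGFBP1 at 12.9 CPM in the authors' deposited table. SCARA5, a ferritin receptor gene that also started near zero, rose by 8.49 ± 0.27, and the ligand gene WNT4 by 4.31 ± 0.17, in the authors' deposited table. The transcription factor genes HAND2 (1.28 ± 0.12) and IRF4 (2.93 ± 0.33) rose too, and BMP2 did not pass (-0.26 ± 0.16, adjusted p = 0.231), in the authors' deposited table. DIO2, which activates thyroid hormone, fell by 2.59 ± 0.18 as the exception in the authors' deposited table.

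Targets shared by the progestin and glucocorticoid receptors rose with EPC in 16 of 22 members and fell in 2, the same counts as when adjusted over the list alone (camera adjusted p = 5.52e-17). The zinc finger gene ZBTB16 (6.77 ± 0.27), the receptor chaperone gene FKBP5 (3.60 ± 0.15) and MAOA (4.88 ± 0.27), which breaks down monoamines, led the list in the authors' deposited table. Of 23 cAMP targets, 13 rose and 3 fell (14 and 3 adjusted over the list alone, camera adjusted p = 1.03e-08). SST, the clock gene PER1 (1.91 ± 0.13) and the mitochondrial coactivator PPARGC1A (2.96 ± 0.22) rose by these amounts in the authors' deposited table. In the insulin and IGF list, 11 of 23 members rose and 3 fell, the same counts as when adjusted over the list alone (camera adjusted p = 1.5e-09). By adjusted p, IGF1 and IGFBP1 led it, followed by the binding protein gene IGFBP2 (2.45 ± 0.14), while HK2, which starts glycolysis, fell by 1.61 ± 0.13 in the authors' deposited table.

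Cell cycle genes were lower with EPC in 43 of 44 members and higher in 0, also when adjusted over the list alone, with a median of -1.28 (camera adjusted p = 6.18e-27). The proliferation marker MKI67 fell by 1.79 ± 0.14, the spindle gene ASPM by 1.59 ± 0.12 and the cytokinesis gene ANLN by 1.41 ± 0.12 in the authors' deposited table. p53 targets fell in 15 of 20 members and rose in 0, also when adjusted over the list alone (camera adjusted p = 1.98e-05). They included the pro-apoptotic gene BBC3 (-1.50 ± 0.15), the stress cytokine gene GDF15 (-1.35 ± 0.15) and the cell cycle inhibitor gene CDKN1A (-0.91 ± 0.12) in the authors' deposited table. Contractile cytoskeleton genes fell in 10 of 17 members and rose in 1 (10 and 2 adjusted over the list alone, camera adjusted p = 0.00011).

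Complement, basement membrane and uterine transcription factor lists were higher with EPC, and angiogenesis genes lower. Complement genes rose in 9 of 14 members and fell in 0 (camera adjusted p = 5.18e-05). Basement membrane genes rose in 10 of 19 and fell in 2 (camera adjusted p = 0.000163), and uterine transcription factors rose in 11 of 26 and fell in 4 (camera adjusted p = 0.000463). Angiogenesis genes fell in 11 of 24 members and rose in 3 (camera adjusted p = 0.00212). In each of these 4 lists the counts were unchanged when adjusted over the list alone. None of the lists for other cell types of the endometrium passed in the main test. Perivascular cell markers had 6 members higher and 4 lower of 11 (camera adjusted p = 0.0832), and passed as higher with log2 fold changes as the statistic (adjusted p = 0.0018). Endometrial epithelium markers had 3 higher and 3 lower of 9 (camera adjusted p = 0.207), and passed as lower without the 25% least expressed genes (adjusted p = 5.75e-05). All 11 lists that passed for the EPC response also passed with a preset correlation of 0.05, with the same direction. Medians, means and tests had 1 sign in every list that passed for the 3 comparisons. They differed in sign in 4, 3 and 9 of the lists that did not, for the EPC response, PGR knockdown and FOXO1 knockdown.

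**Figure D1:**
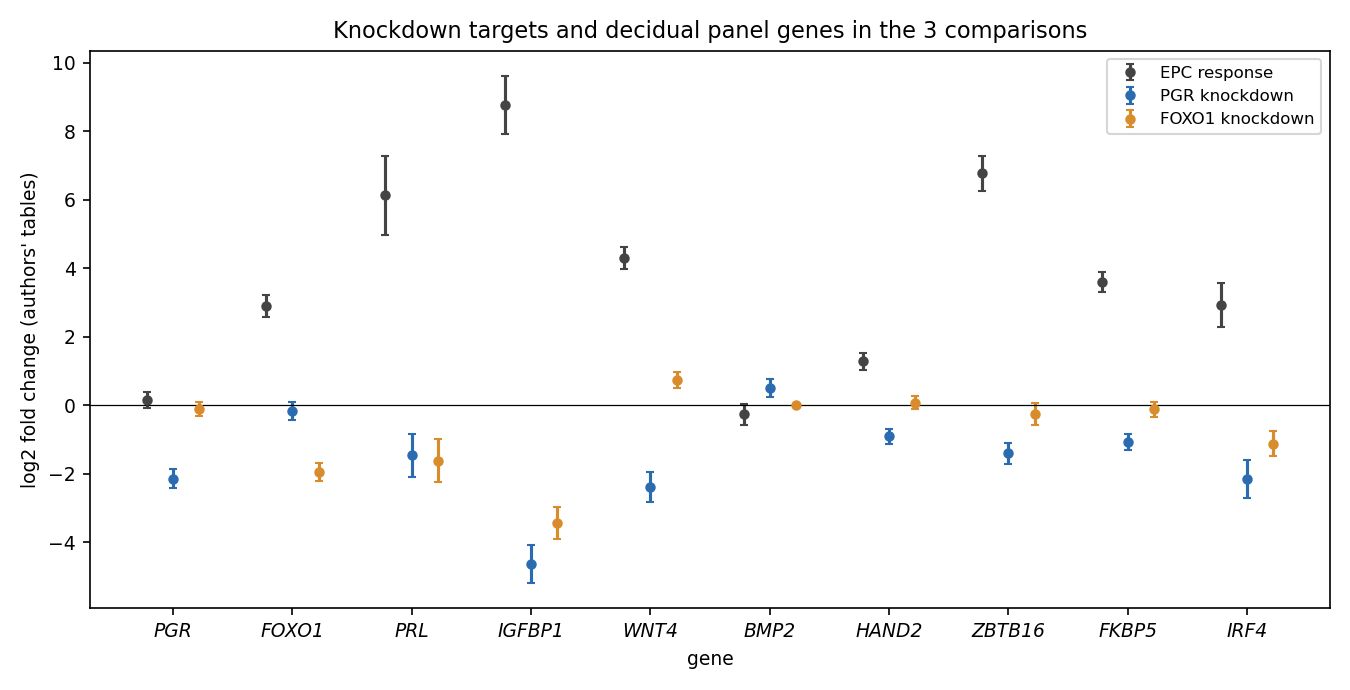
Log2 fold changes of the knockdown targets and the 8 panel genes in the authors' deposited tables, on the vertical axis, for the EPC response (dark), the PGR knockdown (blue) and the FOXO1 knockdown (orange). Bars are 95% intervals from the implied SE; BMP2 has none in the FOXO1 knockdown because its likelihood-ratio score lay under 0.01. WNT4 lies at 4.31 for EPC, -2.38 for siPGR and 0.74 for siFOXO1.

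The next comparison asked which genes changed with siPGR under EPC. IGF1, MYOCD and 12 of 22 decidual markers were lower with siPGR, while 5 of these markers were higher. The glycoprotein hormone gene STC1, 13 of 23 measured cAMP targets and 15 of 27 interferon response genes were higher. Each target had a single siRNA group and no rescue, so loss of the target cannot be separated from other effects of its siRNA. Of 13953 genes, 4960 passed 0.05 in the authors' deposited table, 2484 higher and 2476 lower with siPGR, of which 612 and 408 changed at least 2-fold. Above the median expression, the highest called log2 fold changes in the authors' deposited table were STC1 (4.96 ± 0.17), the fatty acid carrier gene FABP4 (4.11 ± 0.18), the neuropeptide precursor gene VGF (3.89 ± 0.17), KRT34 (2.84 ± 0.20) and KIAA1199 (now CEMIP, 2.84 ± 0.15). KRT34 belongs to a family of close keratin copies, so its reads are uncertain. STC1 went from an implied 38.2 to 1189 CPM in the authors' deposited table. The lowest there were IGF1 (-5.20 ± 0.27), the retinoic acid synthesis gene ALDH1A3 (-4.26 ± 0.23), MYOCD (-4.08 ± 0.15), PARM1 (-2.92 ± 0.14) and the WNT inhibitor gene APCDD1 (-2.90 ± 0.19).

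Decidual markers fell in 12 of 22 members with siPGR and rose in 5 (13 and 5 adjusted over the list alone), with a median of -0.69 (camera adjusted p = 1.02e-05). IGFBP1 fell by 4.62 ± 0.28, WNT4 by 2.38 ± 0.22 and MAOB by 1.99 ± 0.17 in the authors' deposited table. The TGF-beta family gene LEFTY2 fell from an implied 22.5 to 2.81 CPM there (adjusted p = 3.98e-39). Of the panel, IRF4 (-2.15 ± 0.28), PRL (-1.46 ± 0.32) and HAND2 (-0.90 ± 0.12) also fell in the authors' deposited table, while BMP2 rose (0.51 ± 0.13, adjusted p = 0.000399). TIMP3 and SST, the members besides FOXO1 with the highest expression among those not past the threshold, had log2 fold changes of -0.11 ± 0.14 and -0.11 ± 0.15 in the authors' deposited table. The progestin and glucocorticoid receptor list went both ways, with 11 members lower and 8 higher of 22, also when adjusted over the list alone, and did not pass (camera adjusted p = 0.259). In it, ZBTB16 fell by 1.39 ± 0.16 and FKBP5 by 1.07 ± 0.12 in the authors' deposited table.

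cAMP targets were higher with siPGR, with 13 of 23 members up and 4 down (13 and 5 adjusted over the list alone), and a median of 0.70 (camera adjusted p = 4.28e-06). STC1 and VGF were joined by the nuclear receptor gene NR4A1 (2.15 ± 0.15) in the authors' deposited table. EPC itself had not raised these leading members past the threshold in the authors' deposited table. With EPC, STC1 fell by 0.57 ± 0.20, and VGF (-0.20 ± 0.24, adjusted p = 0.591) and NR4A1 (0.38 ± 0.20, adjusted p = 0.156) did not pass. Of the cAMP targets named above as raised by EPC, PPARGC1A (-1.76 ± 0.17) and PER1 (-0.74) were lower with siPGR in the authors' deposited table, and SST did not pass. Contractile cytoskeleton genes rose in 8 of 17 members and fell in 1 (10 and 1 adjusted over the list alone, camera adjusted p = 3.32e-05). CTGF (now CCN2, 2.65 ± 0.13), CYR61 (now CCN1, 1.51 ± 0.12) and the intermediate filament gene DES (1.32 ± 0.20) led them in the authors' deposited table. The first pair encodes secreted matrix-associated proteins rather than filaments. p53 targets rose in 10 of 20 members and fell in 3, also when adjusted over the list alone (camera adjusted p = 0.00122). GDF15 rose by 2.44 ± 0.13 and CDKN1A by 1.32 ± 0.12, while CCNG1 had a log2 fold change of -1.42 ± 0.11, in the authors' deposited table. Interferon response genes rose in 15 of 27 members and fell in 0, also when adjusted over the list alone (camera adjusted p = 0.00122).

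Complement genes fell in 8 of 14 members with siPGR and rose in 2 (9 and 2 adjusted over the list alone, camera adjusted p = 0.000583). The protease genes CFD (-2.35 ± 0.22), C1R (-1.17 ± 0.12) and C1S (-0.92 ± 0.11) had the smallest adjusted p in the authors' deposited table. The insulin and IGF list fell in 11 of 23 members and rose in 3 (11 and 4 adjusted over the list alone, camera adjusted p = 0.000585), a call lost with ranks (adjusted p = 0.079). Besides IGF1 and IGFBP1 its leading member was HK2, which rose by 2.57 ± 0.14 in the authors' deposited table. A further 4 lists passed but were lost with a preset correlation of 0.05. They were basement membrane (12 of 20 lower, 2 higher, adjusted p = 0.00658, and adjusted p = 0.055 at the larger correlation), uterine transcription factors (12 of 26 lower, 2 higher, 0.00708 and 0.0711), FOXO targets (14 of 26 lower, 6 higher, 0.00708 and 0.0711) and sterol synthesis (13 of 25 higher, 0 lower, 0.0125 and 0.092). Adjusted over the list alone, these counts were 13 and 2, 13 and 2, 14 and 6, and 14 and 2. Cell cycle genes did not pass, with 7 of 44 members lower and 2 higher (7 and 1 adjusted over the list alone, camera adjusted p = 0.164). No list of other cell types passed in the main test of this comparison, and endometrial epithelium markers passed as higher without the 25% least expressed genes (adjusted p = 0.00667).

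The FOXO1 comparison asked the same of siFOXO1. Fewer genes changed, and by less: 14 of 20 p53 targets rose, and 19 of 44 cell cycle genes and 11 of 25 listed matrix proteases and inhibitors fell. Of 13787 genes, 1608 passed 0.05 in the authors' deposited table, 664 higher and 944 lower with siFOXO1, of which 131 and 149 changed at least 2-fold. Log2 fold changes had an SD over genes of 0.36, against 0.61 in the PGR knockdown. Above the median expression, the highest called log2 fold changes in the authors' deposited table were SCARA5 (1.56 ± 0.14), the dystrophin gene DMD (1.52 ± 0.14), KCTD12 (1.26 ± 0.10), the actin-binding gene SYNPO (1.23 ± 0.11) and SPATA18 (1.19 ± 0.12). Besides FOXO1 itself, the lowest there were KIAA1199 (-1.97 ± 0.16), the metalloprotease gene ADAM12 (-1.66 ± 0.13), the growth factor gene HGF (-1.54 ± 0.12) and CD24 (-1.41 ± 0.13). CD24 has near-identical pseudogene copies, so its reads are uncertain.

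Decidual markers split under siFOXO1: 9 of 22 members rose and 4 fell, also when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.499). Its median was 0.18 and its mean -0.08. The fallen members include FOXO1, the siRNA target. Without it, an alternative chosen after the data were seen, 9 of 21 members rose and 3 fell, the median was 0.27 and the mean 0.01, and the list passed as higher (camera adjusted p = 0.0326). IGFBP1 fell by 3.44 ± 0.24, PRL by 1.62 ± 0.32 and IRF4, of the panel, by 1.12 ± 0.19 in the authors' deposited table. WNT4 rose by 0.74 ± 0.12 in the authors' deposited table (adjusted p = 5.92e-08). HAND2 (0.08 ± 0.10), ZBTB16 (-0.25 ± 0.17), FKBP5 (-0.11 ± 0.11) and BMP2 (0.01) did not pass in the authors' deposited table.

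p53 targets rose in 14 of 20 members and fell in 0 (17 and 0 adjusted over the list alone), with a median of 0.48 (camera adjusted p = 1.92e-18). CDKN1A rose by 1.13 ± 0.11, the nucleotide synthesis gene RRM2B by 0.98 ± 0.10 and the DNA damage binding gene DDB2 by 0.82 ± 0.12 in the authors' deposited table. Cell cycle genes fell in 19 of 44 members and rose in 1 (22 and 3 adjusted over the list alone), with a median of -0.62 (camera adjusted p = 1.18e-11). MKI67 fell by 1.24 ± 0.14, DLGAP5 by 1.50 ± 0.24 and the mitotic kinesin gene KIF20A by 1.31 ± 0.23 in the authors' deposited table. Matrix proteases and their inhibitors fell in 11 of 25 members and rose in 2, also when adjusted over the list alone (camera adjusted p = 2.85e-09). With ADAM12, the collagen-degrading protease gene CTSK fell by 1.24 ± 0.11 and MMP11 by 1.30 ± 0.15 in the authors' deposited table.

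The insulin and IGF list fell in 4 of 23 members and rose in 0 under siFOXO1 (6 and 1 adjusted over the list alone, camera adjusted p = 5.47e-06). IGF1 fell by 1.15 ± 0.11 and the glucose transporter gene SLC2A12 by 1.16 ± 0.18 in the authors' deposited table. Contractile cytoskeleton genes rose in 5 of 17 members and fell in 0 (7 and 1 adjusted over the list alone, camera adjusted p = 0.000196). They included MYH11 (2.09 ± 0.37), CNN1 (0.53 ± 0.11) and ACTA2 (0.69 ± 0.15) in the authors' deposited table. MYH11 was barely expressed, at an implied 0.359 CPM in siNT EPC and 1.53 CPM in siFOXO1 EPC. ACTA2 shares long stretches with other actin genes and is uncertain. The unfolded protein response list fell in 3 of 20 members and rose in 0 (4 and 0 adjusted over the list alone, camera adjusted p = 0.0135). SEL1L (-0.44 ± 0.11), HYOU1 (-0.35 ± 0.10) and MANF (-0.38 ± 0.11), all of the endoplasmic reticulum, were its fallen members in the authors' deposited table. This list and 8 others passed at the preset correlation of 0.01 and not at 0.05, where its adjusted p = 0.066.

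Those other lists included markers of stromal fibroblasts and of further cell types. Stromal fibroblast markers fell in 3 of 16 members and rose in 0 (adjusted p = 0.0135, and adjusted p = 0.0616 at a correlation of 0.05). Endometrial epithelium markers rose in 2 of 9 and fell in 0 (0.0223 and 0.0616), endothelium markers fell in 2 of 3 (0.0257 and 0.0569) and leukocyte markers in 2 of 4 (0.0277 and 0.0616). Most listed markers of the last pair were not measured: 3 of 14 endothelium and 4 of 17 leukocyte markers were. These calls therefore do not show a change in those cell types. The remaining lists were cAMP targets with 9 of 22 higher and 4 lower (0.0135 and 0.0686), complement with 3 of 14 lower and 0 higher (0.0358 and 0.112), sterol synthesis with 3 of 25 lower and 0 higher (0.0358 and 0.158), and angiogenesis with 3 of 23 lower and 3 higher (0.0398 and 0.158). Adjusted over the list alone, 3 epithelium markers were higher, 10 cAMP targets were higher and 5 lower, and 5 complement and 5 angiogenesis genes were lower. The FOXO target list, with 6 of 26 members lower and 2 higher (7 and 4 adjusted over the list alone), did not pass (camera adjusted p = 0.0767).

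**Figure D2:**
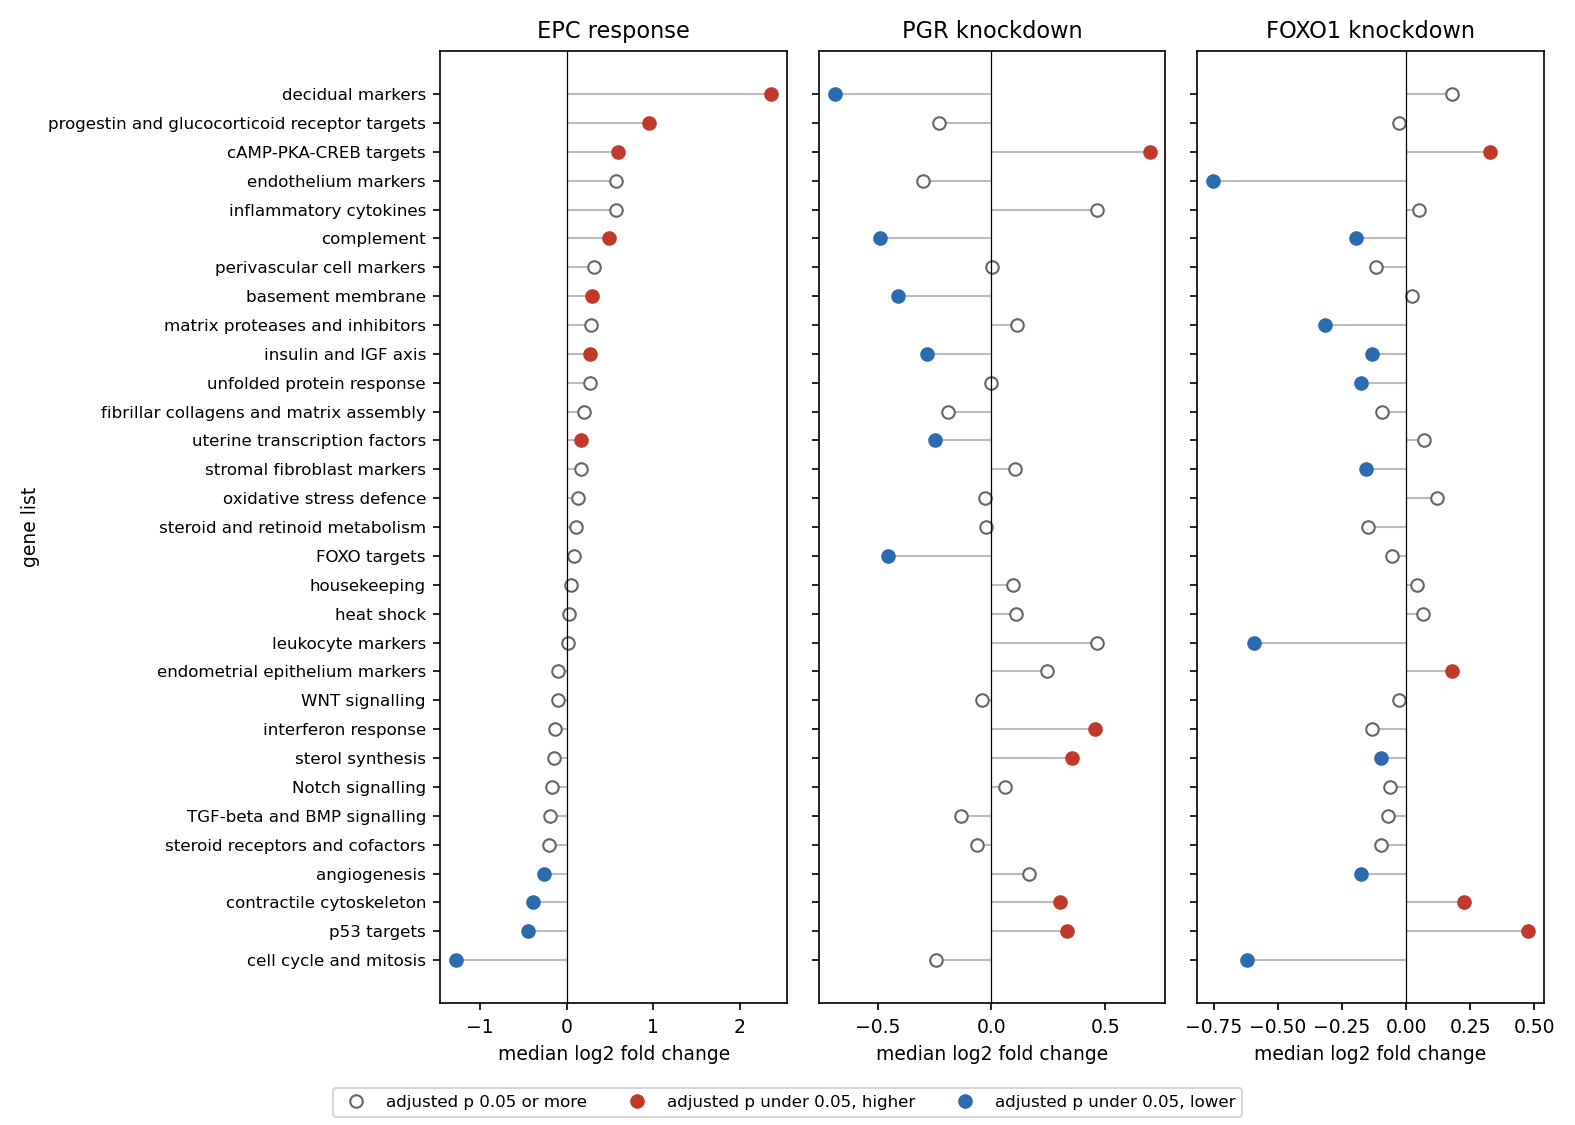
Median log2 fold change of the measured members of each of the 31 gene lists (horizontal axis, with its own scale in each panel) for the EPC response, the PGR knockdown and the FOXO1 knockdown. Filled points passed the list test at an adjusted p under 0.05, red where higher and blue where lower; decidual markers lie at 2.37, -0.69 and 0.18, and cell cycle genes at -1.28, -0.24 and -0.62.

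Setting the EPC response against each knockdown asked how far each knockdown ran against it. FOXO1 mRNA stayed above its vehicle level after siFOXO1, so these counts do not measure how far the response needs FOXO1. Among EPC-responsive genes that passed after PGR knockdown, most moved against the EPC response (1776 against 355), while after FOXO1 knockdown 347 moved against it and 547 with it. Of 1892 genes raised by EPC and tested after siPGR, 789 fell with siPGR and 179 rose. Of 2134 lowered by EPC, 987 rose with siPGR and 176 fell. Independent lists would give 341 and 372 opposed genes and 330 and 384 genes of the same direction. Simulated unchanged groups sharing the siNT EPC libraries gave 0 for this and the overlaps below, but groups without effects yield hardly any calls, so the 0 does not show what the sharing adds among changed genes. Part of the opposed counts may come from the shared libraries. The covariance of log2 fold changes was -0.213 for the EPC response with the PGR knockdown, beside -0.0176 simulated for the shared libraries, a difference of -0.195. Genes raised at least 2-fold by EPC had a median log2 fold change of -0.67 with siPGR, and those lowered at least 2-fold one of 0.77.

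Among the genes raised by EPC and lowered by siPGR, MYOCD, the natriuretic peptide clearance receptor gene NPR3, the cannabinoid receptor gene CNR1, PARM1 and IGF1 ranked first by adjusted p. NPR3 rose by 4.72 ± 0.21 with EPC and fell by 4.19 ± 0.17 with siPGR, and CNR1, near zero without EPC, rose by 8.46 ± 0.29 and fell by 5.22 ± 0.25, in the authors' deposited tables. PARM1 rose by 5.19 ± 0.22 with EPC in the authors' deposited table. In the other direction CTGF fell by 2.70 ± 0.12 with EPC, KIAA1199 by 3.07 ± 0.18, PLXDC2 by 3.02 ± 0.18, FRMD4A by 1.98 ± 0.13 and FGD4 by 2.68 ± 0.18 in the authors' deposited table. With siPGR, PLXDC2 rose by 2.73 ± 0.16, FRMD4A by 1.87 ± 0.11 and FGD4 by 2.91 ± 0.17 in the authors' deposited table.

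After siFOXO1, 222 of 1892 genes raised by EPC fell and 212 rose, while 125 of 2088 lowered by EPC rose and 335 fell. Independent lists would give 131, 88.2, 97.3 and 144, and part of the opposed counts may again come from the shared libraries. The covariance was 0.0171, beside -0.0170 simulated for the shared libraries, a difference of 0.0342. Genes raised at least 2-fold by EPC had a median log2 fold change of 0.01 with siFOXO1, and those lowered at least 2-fold one of -0.20. Besides FOXO1, the genes that led the opposed set by adjusted p were IGFBP1, THSD7A (3.04 ± 0.19 with EPC and -2.23 ± 0.17 with siFOXO1), IGF1 and the TGF-beta co-receptor gene TGFBR3 (1.12 ± 0.12 and -1.23 ± 0.12), from the authors' deposited tables. Lowered by EPC and raised by siFOXO1 were the transcription factor gene ETV1 (-2.73 ± 0.27 and 1.74 ± 0.17), LMO7 (-1.33 ± 0.13 and 0.84 ± 0.10), CDKN1A, the keratin gene KRT18 (-1.32 ± 0.12 and 1.09 ± 0.14) and the cadherin gene CDH2 (-0.76 ± 0.11 and 0.87 ± 0.11), from the authors' deposited tables. KRT18 has many processed pseudogenes, so its reads are uncertain.

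**Figure D3:**
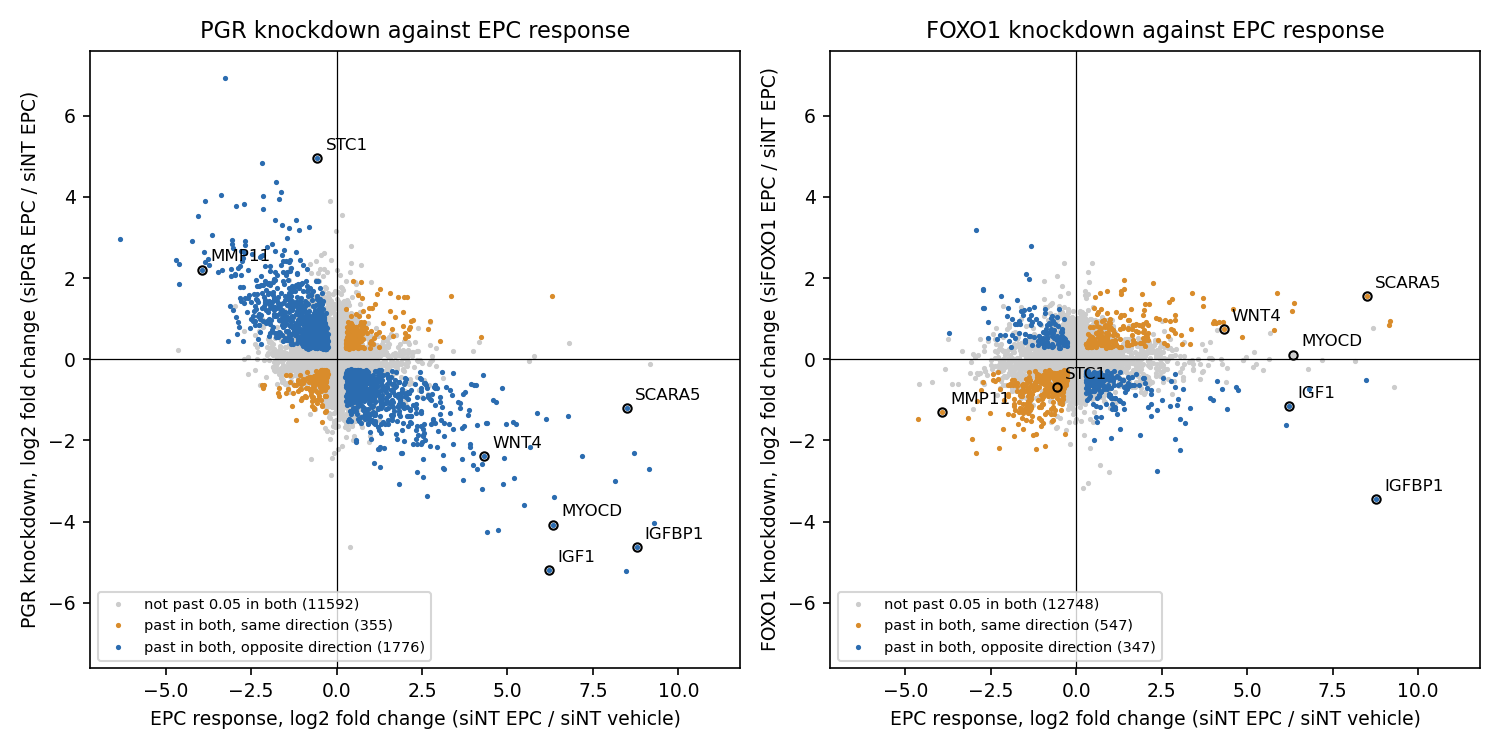
Each point is a gene, with its log2 fold change for EPC on the horizontal axis and for the PGR (left) or FOXO1 (right) knockdown on the vertical axis, from the authors' deposited tables. Blue points passed 0.05 in both with opposite directions (1776 genes left, 347 right) and orange points with the same direction (355 left, 547 right).

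The overlap of both knockdowns asked which genes moved alike with siPGR and with siFOXO1. Over 13693 genes tested in both, 196 rose and 268 fell in both, 249 rose with siPGR and fell with siFOXO1, and 161 did the reverse. Independent lists would give 111, 170, 163 and 117. The covariance was 0.0171, against 0.0172 simulated for the shared libraries without regard to the shared donors. The control group has only 3 libraries and could not be split, so part of the overlap in the same direction may come from it. Genes that led the rise in both by adjusted p were the integrin gene ITGA3 (1.46 ± 0.12 with siPGR and 1.07 ± 0.10 with siFOXO1), ETV1 (1.78 ± 0.17 and 1.74 ± 0.17), CDKN1A, RRM2B (1.01 ± 0.11 with siPGR) and the synaptic gene UNC13A (2.39 ± 0.26 and 1.97 ± 0.25), from the authors' deposited tables. By the same order the fall in both was led by IGFBP1, TGFBR3 (-1.61 ± 0.12 with siPGR), IGF1, the anti-angiogenic gene SERPINF1 (-1.19 ± 0.12 with siPGR, and from 322 to 161 CPM with siFOXO1) and C1QTNF7 (-1.08 ± 0.13 and -1.05 ± 0.11), from the authors' deposited tables.

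Directly between the knockdowns, 1202 of 13693 genes differed by at least 1 on the log2 scale, 554 higher with siFOXO1 and 648 higher with siPGR. Without the 25% of genes with the lowest expression, 580 remained. Genes above the median expression with the largest differences, siFOXO1 minus siPGR, were CNR1 (4.70 ± 0.28), MYOCD (4.19 ± 0.18), ALDH1A3 (4.05 ± 0.25), IGF1 (4.05 ± 0.29) and NPR3 (3.44 ± 0.22), computed from the authors' deposited tables. At the other end stood STC1 (-5.64 ± 0.23), KIAA1199 (-4.81 ± 0.22), MMP11 (-3.51 ± 0.25), the TGF-beta docking receptor gene LRRC32 (-2.97 ± 0.22) and the lipoprotein receptor gene VLDLR (-2.51 ± 0.21), from the same authors' deposited tables. Of the 8 panel genes, WNT4 (3.12 ± 0.25), IGFBP1 (1.18 ± 0.37), ZBTB16 (1.15 ± 0.23), IRF4 (1.03 ± 0.34), HAND2 (0.99 ± 0.15) and FKBP5 (0.96 ± 0.16) were higher with siFOXO1 (adjusted p of the difference from 1.03e-32 for WNT4 to 0.013 for IRF4). BMP2 was lower (-0.50 ± 0.17, adjusted p = 0.0193 in the difference test, with a stand-in SE for siFOXO1). PRL differed by -0.16 ± 0.45 (adjusted p = 0.853 in the difference test). Of 3962 genes called with siPGR and not with siFOXO1, 2311 passed the test of the difference.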

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

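Centring on the most expressed genes, leaving the knockdown target out of the lists and all alternatives for the difference between the knockdowns were chosen after the data were seen; the others were set before the data were examined. With a minimum log2 fold change of 1, the 4061, 4960 and 1608 calls became 1247 for the EPC response, 1020 for the PGR knockdown and 280 for the FOXO1 knockdown, and with Bonferroni adjustment they became 1698, 1756 and 460. An adjusted p under 0.01 left 1063 calls for the FOXO1 knockdown. These settings are stricter by construction. Counts stayed within 1.5 times of the main ones with an adjusted p under 0.1, without the 25% of genes with the lowest expression, and with centring, as did the EPC response and PGR knockdown counts at 0.01. Centring shifted fold changes by -0.02, 0.03 and 0.00 on the log2 scale and moved the share of higher calls from 46.6% to 49.7%, from 50.1% to 45.2% and from 41.3% to 41.1%. Genes moved alike by both knockdowns went from 464 to 291 at 0.01 and to 59 with the minimum fold in both. Genes opposed by siPGR went from 1776 to 430 with that minimum, and those opposed by siFOXO1 from 347 to 221 at 0.01 and 49 with the minimum. The 1202 genes that differed between the knockdowns became 580 without the 25% least expressed, 213 at a difference of 2 and 3456 under the added test with no minimum; 1047 of the 1202 passed that test. Without those 25%, 17 lists passed for the EPC response, in place of 11, with endometrial epithelium markers among the added ones. Without the target, 11 of 11 lists stayed for the PGR knockdown and 14 of 14 for the FOXO1 knockdown, where decidual markers were added. A preset correlation of 0.05 left 7 of 11 lists for the PGR knockdown and 5 of 14 for the FOXO1 knockdown, and ranks left 9 of 14 for the latter; the cause was not tested for the 17 lists or the ranks. No list and no named gene that passed turned its direction under any alternative run. Of 205 named gene results, 22 lost their call with Bonferroni adjustment, 6 at 0.01 and 39 with the minimum fold, and 29 lay among the 25% left out.

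No paired analysis was possible because the deposited tables hold no per-sample values. For the same reason the fit with the donor as a block, leaving out each replicate, DESeq2, other normalizations, other filters on low counts, other pseudocounts, an estimated correlation between genes and other splits of the libraries were not run. How far single donors or libraries carry any result is therefore open. Depth is unknown, and genes near zero in a group have fold sizes that depend on the authors' fit.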

Other observations

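The gene list tests in this part were planned; its other tests, and the genes it names outside the rule, were chosen after the results were seen. Interferon response genes rose with siPGR in 15 of 27 members. OAS1 (1.86 ± 0.28), RSAD2 (1.66 ± 0.35) and IFIT1 (1.25 ± 0.26), all induced by viral RNA and interferon, rose with siPGR in the authors' deposited table, while the signal transducer gene STAT1 had a log2 fold change of 0.06 ± 0.13. Under siFOXO1, 1 of 27 members rose and 3 fell (camera adjusted p = 0.308), and the difference between the knockdowns was not tested for this list. With siPGR, 14 of 26 FOXO targets fell and 6 rose although FOXO1 mRNA did not pass, and the list call (camera adjusted p = 0.00708) was lost at a correlation of 0.05 (adjusted p = 0.0711) and with ranks (adjusted p = 0.0842). The muscle atrophy ligase gene FBXO32 stood at -1.52 ± 0.20 and KLF2, in the other direction, at 1.92 ± 0.22 in the authors' deposited table. Sterol synthesis genes rose with siPGR in 13 of 25 members and fell in 0, but the list call (camera adjusted p = 0.0125) was lost at a correlation of 0.05 (adjusted p = 0.092) and with log2 fold changes as the statistic (adjusted p = 0.0764). Risen members included HMGCS1 (1.04 ± 0.15) and SQLE (0.67 ± 0.13) in the authors' deposited table. ALDH1A3, among the lowest with siPGR, had risen by 4.40 ± 0.41 with EPC in the authors' deposited table, and had a log2 fold change of -0.21 ± 0.10 with siFOXO1 (adjusted p = 0.209).

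The EPC response of vessel and matrix genes was mixed. THBS1, which inhibits vessel growth, fell by 2.20 ± 0.14 with EPC, while VEGFA rose by 0.63 ± 0.13 and HIF1A by 1.11 ± 0.12 in the authors' deposited table. The basement membrane collagen gene COL15A1 rose by 3.15 ± 0.14 with EPC and fell by 1.56 ± 0.14 with siPGR in the authors' deposited tables. STC1, counted among cAMP targets, fell with EPC (-0.57 ± 0.20, adjusted p = 0.0152) and rose with siPGR above its vehicle level, at an implied 61.3, 41.3, 1189 and 25.2 CPM in siNT vehicle, siNT EPC, siPGR EPC and siFOXO1 EPC, levels set across the authors' deposited tables, which were normalized separately. Of the markers of other cells that moved with siFOXO1, the receptor genes KDR (-1.16 ± 0.17) and TEK (-0.75 ± 0.22) and the lysosomal gene CD68 (-0.80 ± 0.11) fell, and KRT7 rose (0.82 ± 0.26), in the authors' deposited table. The matrix proteoglycan gene DCN, a stromal marker, fell by 0.95 ± 0.16 there.

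More genes passed after PGR than after FOXO1 knockdown. Smaller error in the PGR table is argued against, since the implied SE in that table divided by the SE in the FOXO1 table had a median of 1.02 over 12421 genes (25th to 75th percentile 0.968 to 1.06). A deeper knockdown of PGR mRNA stays open: the log2 fold change of PGR lay below that of FOXO1 by a difference of -0.19, with a 95% interval from -0.57 to 0.19. A wider reach of PGR under EPC is a hypothesis that these tables cannot separate from unequal loss of protein, which was not measured here. FOXO1 mRNA also stayed above its vehicle level after siFOXO1, while PGR mRNA fell below its own after siPGR.

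PGR knockdown ran opposite to the EPC response. The shared siNT EPC libraries alone would give the FOXO1 knockdown the same covariance with the EPC response, but the covariance with the PGR knockdown lay below it, with a difference of -0.230, where simulated covariances spanned 0.00231. A candidate explanation is loss of receptor-driven transcription, which would weigh on progestin targets more than on cAMP targets. Genes in both lists were left out of this contrast. Among the remaining members raised by EPC, 14 progestin and glucocorticoid receptor targets had a mean log2 fold change of -0.76 (SD 0.95) with siPGR and 11 cAMP targets one of 0.05 (SD 0.92), with p = 0.0383 in a two-sided exact permutation test over genes, which are not independent replicates. Of the former 10 fell and 2 rose, and of the latter 3 fell and 4 rose.

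p53 targets were lower with EPC and higher after both knockdowns, so low levels in the shared siNT EPC libraries alone might produce all 3 results. Of all 20 members, 9 changed differently between the knockdowns in the difference test, adjusted over the list alone. Adjusted over all genes, 3456 of 13693 passed the same test. The adjustments differ, so this share is not like for like with the 9 of 20. For these 9 members the shared libraries alone are argued against as the source of both changes, though the libraries may still add to a common rise. Most of the 9 did not rise after both knockdowns, and those members do not bear on what caused a common rise. Among the 9, GDF15 rose by 2.44 ± 0.13 with siPGR and 0.58 ± 0.12 with siFOXO1, and CCNG1 had log2 fold changes of -1.42 ± 0.11 and 0.41 ± 0.11, in the authors' deposited tables. A partly different set of 9 members rose after both, and 8 of them fell with EPC. Of this set, 3, with GDF15 among them, differed between the knockdowns when adjusted over the set. For these 3, this argues against the shared libraries alone, but not against a part of the rise coming from them. FAS, among the 3, was not lower with EPC, at an implied 43.0 CPM in siNT vehicle and 46.7 CPM in siNT EPC. For the other 6 as a set, all lower with EPC, the shared libraries cannot be told apart from an effect of the knockdowns. Low shared libraries alone would leave both knockdown groups at the vehicle level. The median absolute log2 distance of their mean from vehicle was 0.20 over these 6, between 1 and 2 times a median SE bound of 0.16. The siNT EPC group cancels in this distance, but the bound still counts its error. It is therefore too wide if the implied SEs are right, and the distance cannot decide, while no values per library are given. For 1 of the 6 the distance was above 2 times its own SE bound.

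Cell cycle genes were lower after FOXO1 knockdown, and a hypothesis was that mitotic genes carried the fall. The 32 mitotic members had a mean log2 fold change of -0.69 (SD 0.36) and 12 DNA replication members one of -0.10 (SD 0.51), with p = 0.00024 in a two-sided permutation test with 100000 resamples. This test runs over genes, which are not independent replicates, so its p-values do not measure the spread between libraries. Of the mitotic members 16 fell and 0 rose, and of the replication members 3 fell and 1, PCNA (0.52 ± 0.13 in the authors' deposited table), rose. With EPC the means were -1.33 (SD 0.29) and -0.92 (SD 0.43), with p = 0.00134 in the same permutation test. With siPGR they were -0.26 (SD 0.29) and -0.09 (SD 0.29), with p = 0.104 in the same permutation test, which did not pass.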
